A study of Rattus norvegicus with 12 samples.

How the data were processed

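RNA was measured in 12 libraries from Wistar rats: 6 from ordinary ileum and 6 from ileal Peyer's patch, each tissue with 3 control and 3 antibiotic-treated libraries. Per the labels' protocols, the treated rats drank a cocktail of vancomycin and polymyxin B, antibiotics not absorbed from the gut, together with sucrose. The controls drank sucrose alone. Dosing began 1 day before the animals were killed. Poly(A) RNA was selected and libraries were made with a directional kit, per the labels' protocols. Per the submitters' processing notes, the authors used fastp 0.20.1, HISAT2 2.2.1, featureCounts 1.6.4, DESeq2 and the rat build rn6. The DESeq2 version, the gene annotation, the strand setting of the counting and the rule for low genes are not given in the sources used here.

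The authors deposited 1 table per tissue, with 16388 genes for ileum and 16975 for Peyer's patch. Per the file headers, each holds a column of expression values per library, the authors' log2 fold change of control over antibiotics, and their adjusted p-value. The per-library values were found to be log2(normalized count + 4). Undoing that step gave, in every library, whole multiples of the value of 1 read for 100% of the deposited values, to within a tolerance of 1e-07. The size factors recovered this way equal median-of-ratios factors computed within each table, so the 2 tissues were normalized separately by the authors. Tests were therefore made within a tissue, or on the difference between the 2 within-tissue log2 changes, in which a scale common to a table drops out. Levels across tissues are given only as values, after size factors had been recomputed. They rest on the 15052 genes with reads in all 12 libraries, among the 15763 that both tables hold.

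The recovered depth was 10250573 to 12663020 reads per library in ileum and 10526088 to 13054937 in Peyer's patch. The 20 most abundant genes took 11.8% to 15.3% of the reads in ileum and 9.03% to 12.0% in Peyer's patch. The median standard error of a gene's log2 change was 0.13 in ileum and 0.19 in Peyer's patch. For the difference between the tissues' responses it was 0.25. These values hold counting error and the spread between the 3 libraries of a group together, and the parts were not separated. For genes with a mean over 100 counts they were 0.11, 0.16 and 0.20. Genes whose reads can fall on a near-identical copy are uncertain, since the counting could split them.

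Gene names came from the files for 13930 ileum and 14168 Peyer's patch genes. The remaining symbols were matched to a RefSeq gene list of assembly GRCr8 by symbol (938 and 1068 genes) or synonym (318 and 329 genes), and 1202 and 1410 stayed as the files give them. No coordinates are printed, because that assembly is not the build the reads were aligned to.

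The comparisons, tests, gene lists and the rule for naming genes were fixed before the data were examined. The count test of that plan needs raw counts, and it was not run on the whole reads recovered here. As the plan provides for tables of normalized values, limma 3.58.1 in R 4.3.3 with its trend option was applied to log2(normalized count + 1). A fold change is on that scale and understates the change of genes with low values. Genes with at least 10 normalized counts in at least 3 libraries were tested, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each tissue was fitted on its own 6 libraries. The difference between the tissues' responses was tested as the interaction in one fit of all 12 libraries with 4 groups. The plan also held tests of Peyer's patch against ileum in control and in treated rats. They were not run, because the tables were normalized separately, although the recovered reads were put on 1 scale to give levels as values.

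For each antibiotic comparison, the named genes are the 12 called genes with the largest and the 12 with the smallest log2 change, among genes with a symbol whose 3 treated values all lie on one side of the 3 controls. Where fewer than 5 genes are called, the 10 smallest p-values are named as well, as values. For each gene list, up to 4 members are named: the called ones with the smallest p, otherwise those with the smallest p, as values. For the interaction the rule takes 8 in each direction. Genes outside the rule are marked as chosen after their values were seen.

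There were 30 lists of pathway genes and of markers for cell types that a piece of gut wall can hold. Lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, then with a correlation estimated per list, and with fry, which asks whether a list's genes move on balance one way. Benjamini-Hochberg adjustment ran over the lists of a comparison. The list tests of the interaction were not part of the plan.

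Each step was tested on simulated data made from the real means and depths. In ileum it recovered 65.2% of genes changed 1.5-fold, 80.0% of those changed 2-fold and 98.5% of those changed 4-fold, among 14100 genes with 7 false calls. In Peyer's patch it recovered 53.8%, 72.7% and 96.9%, among 14464 genes with 10 false calls. For the interaction it recovered 25.4%, 65.7% and 92.4%, among 14806 genes with 4 false calls. In each comparison camera called 5 of 5 simulated lists shifted by 1.5-fold and 0 of 25 unshifted ones. Genes were drawn independently, at the median dispersion of genes of like abundance. The simulated lists thus held no inter-gene correlation, while estimates for real lists reached 0.70 for enterocyte and 0.96 for mitochondrial genes in Peyer's patch. The 0 of 25 therefore cannot vouch for the camera calls below, nor the recovery rates for genes that move together or vary more.

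The alternatives fixed in advance were quantile normalization, no filter, pseudocounts of 0.5 and 5, a block by replicate number or animal code, a 2-fold minimum, 1 fit of both tissues and leaving out each library in turn. Count-based size factors and a count-based Wald test were in that plan too and were not run. The deposited values are normalized, and the reads recovered from them were used for voom but not for these. Alternatives chosen after the data had been seen were limma voom on the recovered reads, a pseudocount of 4, the mean of the B cell or of the smooth muscle markers as a covariate, and leaving out genes that jump 8-fold or more between libraries of a group. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

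Libraries of a group were taken to be separate animals, as the codes C1 to C3 and A1 to A3 imply. The labels do not say how the animals relate otherwise, nor that a code shared by both tissues names 1 animal. The p-values measure the spread between these samples. No pair of libraries in a group looked like a copy of another: over the 12 pairs, chi-square per degree of freedom was 7.30 to 43.3.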

Results

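Poly(A) RNA was sequenced from 2 parts of the rat small intestine, ordinary ileum and the Peyer's patch of the ileum. Peyer's patches are lymphoid follicles in the gut wall, rich in B cells and covered by an epithelium that takes up luminal antigen. Wistar rats drank vancomycin and polymyxin B, antibiotics that stay in the gut lumen, with sucrose, or sucrose alone, beginning 1 day before they were killed. Each combination of tissue and treatment had 3 libraries, giving 12 in all. Depth was 10250573 to 12663020 counted reads per ileum library and 10526088 to 13054937 per Peyer's patch library.

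The libraries carried the cell markers of their tissues. In control rats the B cell markers were a median of 38.2-fold higher in Peyer's patch than in ileum, with 16 of 16 markers higher there, and T cell markers were 7.83-fold higher. Absorptive enterocyte markers were 3.21-fold higher in ileum, Paneth cell markers 4.44-fold and smooth muscle markers 3.20-fold. The B cell gene Ms4a1 had 9.75 ± 2.32 normalized counts in control ileum and 3107 ± 1054 in control Peyer's patch (SD, n = 3). The apolipoprotein gene Apoa1 of enterocytes had 26631 ± 3883 and 7049 ± 2045 (SD, n = 3). The authors normalized the tissues separately, so these levels rest on size factors recomputed over shared genes with reads in all 12 libraries. They were not tested.

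In a principal component analysis of ileum, the first component held 32.2% of the variance and separated the groups, with controls at 19.3 to 25.3 and treated libraries at -28.6 to -18.5. In Peyer's patch the first component held 44.0% and did not separate them. There controls 1 and 2 lay at 34.5 and 39.5, control 3 at -21.6, and antibiotics 1, 2 and 3 at 8.80, -45.9 and -15.4.

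**Figure D1:**
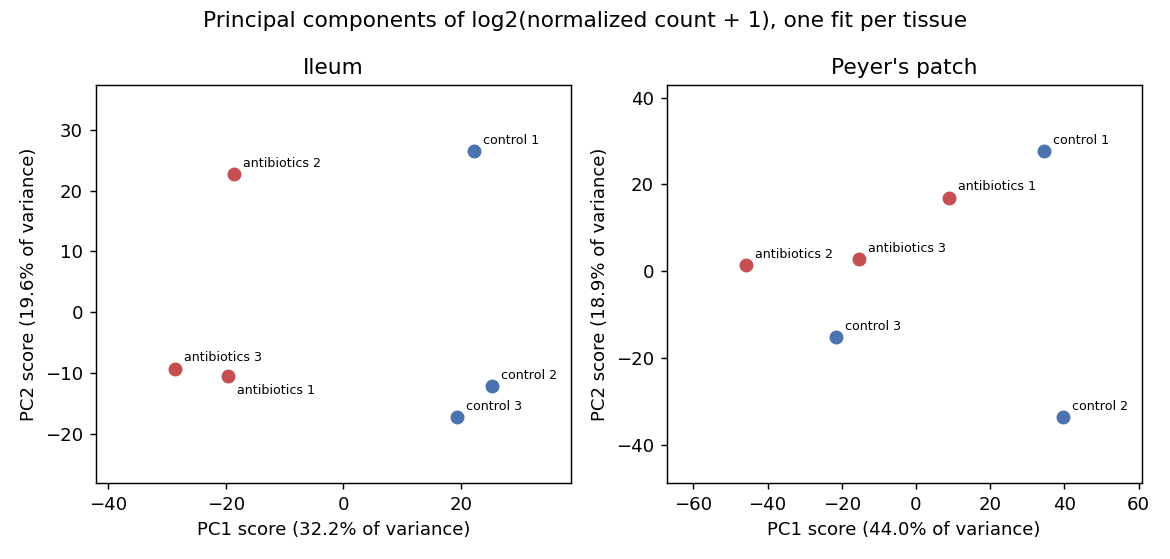
Principal component scores of the 6 libraries of each tissue, from log2(normalized count + 1), with each axis giving its share of variance. The groups separate along the first component in ileum, and in Peyer's patch control 3 lies among the treated libraries.

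The comparison of treated with control ileum asks how pieces of ordinary ileum, muscle included, differ after the rats drank antibiotics. Of 16 microbe-responsive epithelial defence genes, 9 were called lower in the treated ileum (adjusted p = 0.232 for the list with an estimated correlation). Duoxa2 (ENSRNOG00000017805), needed to mature the hydrogen peroxide-producing oxidase Duox2, had 1771 ± 122 normalized counts in controls and 572 ± 121 under antibiotics (SD, n = 3). Nos2, the inducible nitric oxide synthase, a name that 2 genes of the tables share, had 137 ± 44.3 and 15.7 ± 11.2, a log2 change of -3.28. Of 24 proliferation genes 15 were called lower (adjusted p = 0.232 for the list with an estimated correlation), among them Rrm2, a subunit of the enzyme that makes deoxyribonucleotides, at 755 ± 28.7 and 507 ± 30.4. In the other direction, Pck1 (ENSRNOG00000028616), which catalyses a committed step of gluconeogenesis, had 71.9 ± 12.5 in controls and 813 ± 179 under antibiotics.

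Among 14254 genes tested in ileum, limma called 944 at a Benjamini-Hochberg adjusted p under 0.05. Of these, 359 were higher and 585 lower under antibiotics, and 96 differed at least 2-fold. The groups did not overlap for 4170 genes, 29.3% of those tested, where chance gives 10%. The count fell to 305 without control 2, to 447 without control 3, to 447 without antibiotics 1 and to 431 without antibiotics 3, and was 227 in 1 fit of both tissues. With the smooth muscle marker mean as a covariate, chosen after the data had been seen, it was 284, of which 262 were among the 944. The authors' deposited table calls 1224 genes at the same threshold. Of the 1221 tested here, limma called 889 too. All 1221 had the same sign, which is not independent support because the counts are the same.

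The genes named by size of change included several of metabolism and transport among the higher ones. Pck1 rose by 3.47 ± 0.18 on the log2 scale (SE, limma adjusted p = 2.59e-05), and G6pc, the last enzyme of glucose release, rose by 3.37 ± 0.75 from 3.28 to 32.9 counts. Angptl4, a secreted inhibitor of lipoprotein lipase, rose by 1.76. Abcb1a, the drug efflux pump P-glycoprotein, rose by 1.44, from 1641 ± 527 to 4375 ± 1144 counts, and the folate receptor gene Folr1 rose by 1.40. Best2, Tnr, Nphs1, Dchs2, Prss35 and Zfhx4 rose by 2.73, 2.15, 1.98, 1.54, 1.51 and 1.48. G6pc, Best2, Tnr, Nphs1, Angptl4, Dchs2 and Zfhx4 had low counts in both groups, with means of at most 62.6 under antibiotics. Capns1, a calpain subunit, had the largest value, 4.69 ± 0.85, but its treated libraries ranged from 53.1 to 1067 counts, so its level is uncertain.

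Among the lower genes, Fga, the fibrinogen alpha chain, fell by 4.84 ± 0.65 on the log2 scale (SE, limma adjusted p = 0.00353), and complement C9 fell by 2.09. Crabp2, a retinoic acid carrier, fell by 4.17 ± 0.49, from 51.7 ± 12.6 to 2.23 ± 2.04 counts. The ileal hormone gene Fgf19, which bile acids induce, fell by 3.47 ± 0.72. Reg1a, a secreted lectin-like protein, Chac1, a glutathione-degrading enzyme, and LILRB3A, a leukocyte receptor, had log2 changes of -2.61, -2.59 and -2.43. Ido1, which breaks down tryptophan, fell from 21.9 ± 13.1 to 3.13 ± 2.25 counts. Socs3, a feedback inhibitor of cytokine signalling, fell by 2.01 ± 0.20. Ncbp2 and Rpl10l fell by 3.26 and 2.55, both uncertain: control 1 had 10.7 counts of Ncbp2 beside 92.4 and 97.8 in the other controls, and Rpl10l is a near copy of another ribosomal protein gene. Of the 24 genes in these lists of largest changes, 12 stayed called without each library in turn, among them Pck1, Fga, Crabp2, Nos2 and Socs3. Leaving out control 2 ended 9 of the 24 calls, antibiotics 3 ended 6, antibiotics 1 and control 3 ended 5 each, control 1 ended 3 and antibiotics 2 ended 2, at adjusted p up to 0.125. Of all 63 called genes that the rule names in ileum, lists included, leaving out control 2 ended 26 calls, antibiotics 3 ended 20, control 3 ended 18, antibiotics 1 ended 16, control 1 ended 10 and antibiotics 2 ended 8, at adjusted p up to 0.153.

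**Figure D2:**
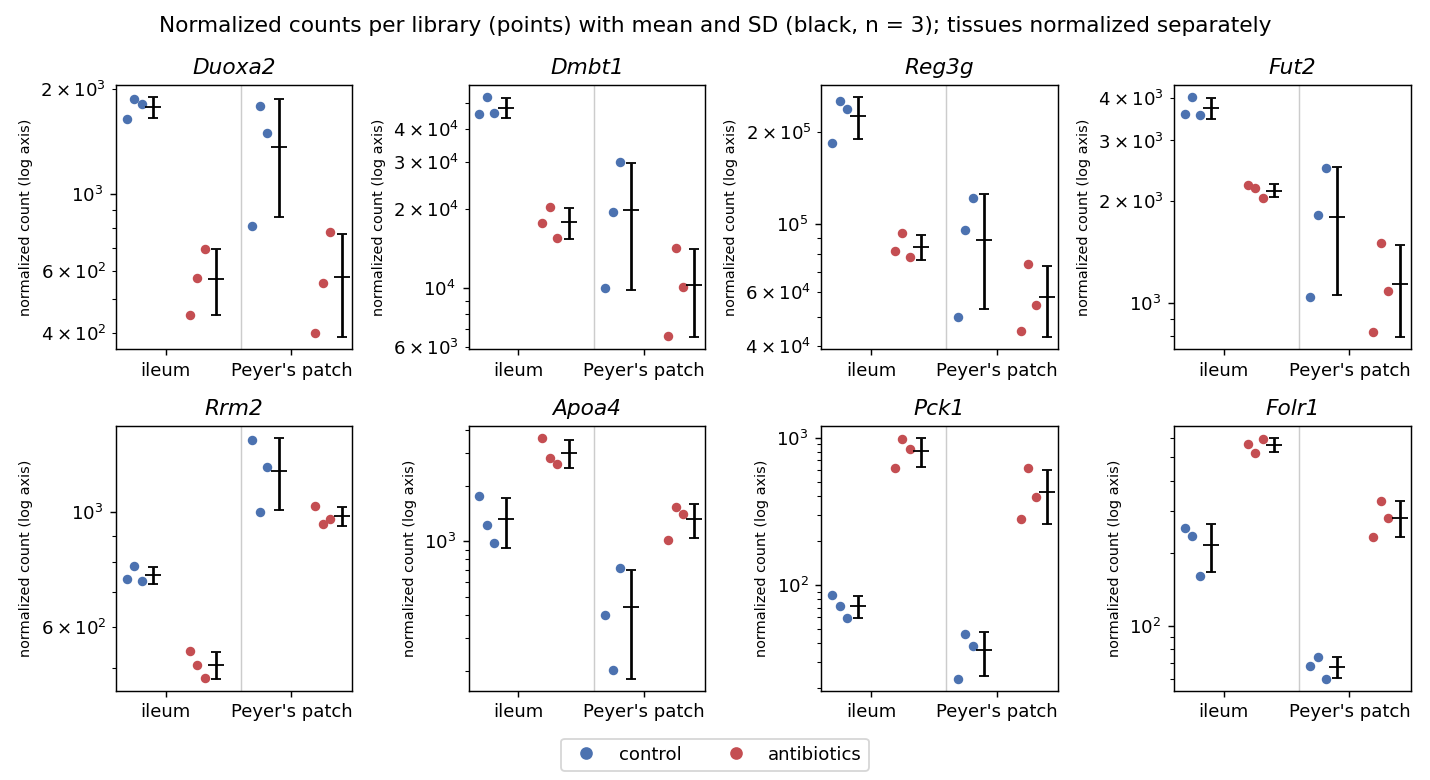
Normalized counts per library on a log axis for 8 genes, with the mean and SD of each group of 3. Treated and control libraries do not overlap in ileum for any of these genes; Reg3g was chosen after its values were seen, and the tissues were normalized separately.

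The microbe-responsive defence genes fell as a list in ileum, and 9 of 16 were called lower and 0 higher (11 lower, adjusted over the list alone). By camera the adjusted p was 1.51e-09, by fry 0.00534, and the adjusted p = 0.232 with an estimated correlation. Duoxa2 fell by 1.65 ± 0.14, Dmbt1, a mucin-like protein that binds bacteria, by 1.44 ± 0.12, Duox2 by 0.93 ± 0.08, and the fucosyltransferase gene Fut2 by 0.80 ± 0.08 on the log2 scale. The antibacterial lectin genes Reg3b and Reg3g, chosen after their values were seen, were among the most abundant transcripts, at 249456 ± 37704 and 224509 ± 35460 counts in control ileum. Both fell, to 88084 ± 9827 and 84496 ± 7997 (SD, n = 3; limma adjusted p = 0.00260 and 0.00312). Among Paneth cell markers, a list that was not called (camera adjusted p = 0.0890), the phospholipase gene Pla2g2a fell by 0.93 and the metalloproteinase gene Mmp7 by 0.42, the 2 called of 12.

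Proliferation genes fell in ileum: 15 of 24 were called lower, 18 when adjusted over the list alone. The camera adjusted p was 5.60e-11 and fry gave 0.00534, with adjusted p = 0.232 with an estimated correlation. Rrm2 fell by 0.58 ± 0.08, the mitotic gene Birc5 by 0.52 ± 0.09, the cyclin-dependent kinase Cdk1 by 0.42 ± 0.08 and the replication helicase gene Mcm3 by 0.52 ± 0.10. The stem cell markers did not move as a list (camera adjusted p = 0.712), with 1 of 13 called, the proliferation-linked Cdca7 at -0.35.

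Absorptive enterocyte markers rose in ileum by a median log2 of 0.39, with 4 of 22 called higher and 13 adjusted over the list alone. The camera adjusted p was 7.45e-06, and the adjusted p = 0.728 with an estimated correlation. The called members were Apoa4 and Apoa1, which coat newly made lipoproteins, at 1.21 ± 0.19 and 0.60 ± 0.12, the glucose transporter gene Slc5a1 at 0.61 ± 0.10 and the fatty acid carrier gene Fabp2 at 0.95 ± 0.19. Plasma cell markers fell (camera adjusted p = 0.00132, and adjusted p = 0.534 with an estimated correlation), with 2 of 12 called and 5 adjusted over the list alone. Those 2, Creld2 at -0.89 and Sec11c at -0.58, act in protein folding and secretion in many cell types. The camera calls of the defence, proliferation, enterocyte and plasma cell lists held without each library in turn. Fry called 2 of the 29 lists in ileum, the defence and proliferation lists. Its adjusted p was 0.170 for the enterocyte, 0.101 for the plasma cell, 0.346 for the interferon and 0.101 for the NF-kB list.

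Interferon-stimulated genes fell as a list by camera (adjusted p = 0.00383, and adjusted p = 0.809 with an estimated correlation). Of 35 members 6 were called lower and 1 higher, or 9 lower and 1 higher adjusted over the list alone. Igtp, an interferon-induced GTPase, fell by 1.24 ± 0.11, the T cell chemoattractant gene Cxcl9 by 1.54 ± 0.19 and Gbp2 by 0.80. Inflammatory NF-kB genes fell (adjusted p = 0.0173, and 0.355 with an estimated correlation), with 2 of 17 called, Socs3 and Nfkbiz at -0.61, and 4 adjusted over the list alone. Without antibiotics 1, the adjusted p was 0.0986 for the interferon list and 0.0563 for the NF-kB list.

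A further 5 lists had smaller camera calls in ileum. Cholesterol synthesis genes were higher with 0 of 24 called (adjusted p = 0.0173; 0.809 with an estimated correlation), led by Tm7sf2 at 0.33 and Hmgcs1 at 0.38. MHC class II genes were lower with 0 of 15 called (adjusted p = 0.0188; 0.809 with an estimated correlation), led by Ifi30 at -0.31. Fatty acid oxidation and PPAR target genes were higher (adjusted p = 0.0191; 0.809 with an estimated correlation), with Angptl4 alone called of 22 and 6 adjusted over the list alone. Smooth muscle markers were higher with 0 of 16 called, led by Kcnmb1 at 0.30 (adjusted p = 0.0191; 0.809 with an estimated correlation). Circadian clock genes were higher (camera adjusted p = 0.0292, and 0.529 with an estimated correlation), with 12 of 16 members positive. Npas2 at 0.68 and Tef at 0.59 were the 2 called, with 3 adjusted over the list alone. The time of day of sampling is not given in the sources used here. No member of the cholesterol, MHC class II or smooth muscle lists was called over the list alone either. Each of these 5 calls was lost without at least 1 library. The cholesterol call ended without control 2, control 3, antibiotics 1 or antibiotics 2 (adjusted p up to 0.296), the clock call without control 1 (0.173) or antibiotics 1 (0.0563), and the MHC class II call without control 1 (0.302) or antibiotics 1 (0.0647). The PPAR call ended without control 3 (0.198) or antibiotics 2 (0.0834) and with no filter (0.0591), and the smooth muscle call without control 2 (0.443) or antibiotics 2 (0.114).

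The other lists tested in ileum were not called, at camera adjusted p from 0.0890 to 0.972, though some held called genes. Bile acid handling genes went both ways: of 13, 4 were called higher, among them the detoxifying enzymes Cyp3a9, Ugt1a1 and Cyp3a62 at 0.89, 1.21 and 0.42, and 1 lower, Fgf19. Their median was -0.05 and their mean -0.16, while camera leaned up (adjusted p = 0.712). The glutathione transferase gene Gstm1 rose by 1.02 and the heme oxygenase gene Hmox1 fell by 0.83, the 2 called of 21 aryl hydrocarbon receptor and xenobiotic genes. Among lymphocyte lists, Cd38 and Gcsam of the germinal centre markers fell by 0.65 and 0.66 and the T cell costimulator gene Icos by 0.80. For B cell markers 0 of 16 were called (camera adjusted p = 0.862), with Ms4a1 at 0.72 ± 0.41, and 0 of 12 cytotoxic lymphocyte markers were called (0.0926), with Gzma at -0.52. The macrophage and dendritic, neutrophil and mast cell, fibroblast and endothelial, Th17 and mitochondrially encoded lists held 0 called genes. By camera, the mitochondrial list was called lower in 3 of 10 other settings, among them a block by replicate number (0.0281). The cytotoxic list was also called lower in 3 of 10, among them quantile normalization (0.0424). Tac1 of the neuron list fell by 1.23, the hormone gene Sct of the enteroendocrine list by 0.45 and Tnfaip2 of the M cell list by 0.87. Rep15 and Agr2 of the goblet list moved by 0.45 and -0.53, and Jun and Junb of the immediate early list by 0.51 and -0.34. Red blood cell genes had fewer than 5 tested members.

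**Figure D3:**
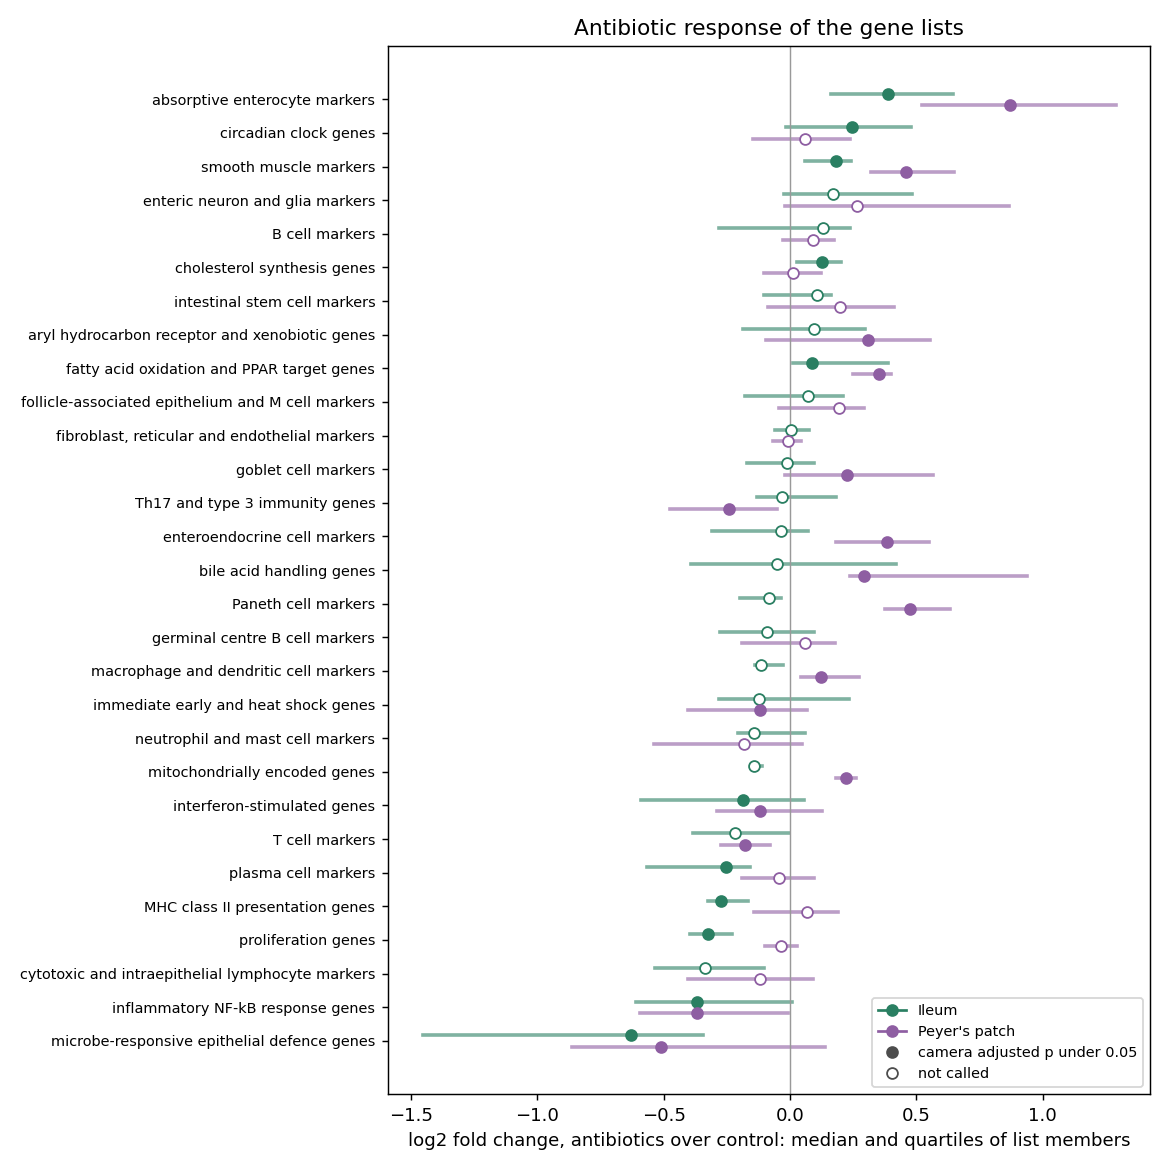
Median (points) and quartiles (lines) of the log2 fold change, antibiotics over control, over the tested members of each gene list. Filled points mark lists with a camera adjusted p under 0.05, none of which keeps it with an estimated correlation.

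The comparison within Peyer's patch asks the same question of the lymphoid tissue. Folr1 and Pck1, called in ileum, were called here too. Folr1 (ENSRNOG00000019902) had 67.3 ± 6.79 normalized counts in controls and 281 ± 48.3 under antibiotics, and Pck1 had 35.8 ± 11.7 and 430 ± 172 (SD, n = 3). Absorptive enterocyte markers were higher as a list, by a median log2 of 0.87, and inflammatory NF-kB genes were lower, with a median of -0.37. Neither list had a member called over all genes, and each had an adjusted p = 0.663 with an estimated correlation. Fry called 0 of the 29 lists in Peyer's patch, at adjusted p of at least 0.545. In all, limma called 4 of 14644 genes at a Benjamini-Hochberg adjusted p under 0.05, 3 higher and 1 lower.

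Pck1 rose by 3.53 ± 0.34 (SE, limma adjusted p = 0.0315) and Folr1 by 2.04 ± 0.18 (limma adjusted p = 0.0283) on the log2 scale. LOC100912481 rose by 3.86 ± 0.28, from 34.9 ± 10 to 519 ± 157 counts, and Aldh18a1 (ENSRNOG00000060047), an enzyme of proline synthesis, fell by 3.52 ± 0.35, from 117 ± 32.5 to 9.37 ± 3.31. Both are uncertain: a pair of genes carries the name LOC100912481, and Aldh18a1 had 2.92, 316 and 2.93 counts in the 3 control ileum libraries. The next smallest p-values, none passing (limma adjusted p = 0.140), belonged to Dnase1 at 2.26, IRG1, an itaconate-producing enzyme of macrophages, at -1.86, the sucrase-isomaltase gene Si at 1.23, the T cell checkpoint gene Lag3 at -0.97, Fabp2 at 1.44 and Abcc2 at 1.39. At an unadjusted p under 0.05 there were 890 genes, and the groups did not overlap for 11.2%, where chance gives 10%. The authors' deposited table calls 97 genes, 60 of them higher under antibiotics. Of the 89 tested here, limma called 4. All 89 had the same sign, from the same counts. All 4 calls were lost without control 2, antibiotics 2 or antibiotics 3 (adjusted p up to 0.206), 3 without control 1 and Aldh18a1 without antibiotics 1 (0.0503). With voom on the recovered reads 0 were called, against 879 at an unadjusted p under 0.05; without control 3 there were 12 calls, without antibiotics 1 there were 7 and without control 1 there were 2. One fit of both tissues called 25, and the B cell or smooth muscle marker mean as a covariate, chosen after the data had been seen, 626 and 0.

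Of the enterocyte markers in Peyer's patch, 0 of 22 were called over all genes by limma and 11 adjusted over the list alone. The camera adjusted p was 1.23e-15, and the adjusted p = 0.663 with an estimated correlation. Fabp2 had 1.44 ± 0.20, Apoa1 1.34 ± 0.26, the fructose transporter gene Slc2a5 1.84 ± 0.37 and Apoc3 1.59 ± 0.32. Fatty acid oxidation and PPAR target genes were higher (camera adjusted p = 1.78e-08, and adjusted p = 0.663 with an estimated correlation) with 0 of 22 called either way, led by Acadm at 0.45 and Creb3l3 at 1.19. Bile acid handling genes were higher (0.000340, and 0.663 with an estimated correlation), 4 of 13 over the list alone: Abcc2, Cyp3a9 at 1.41, Ugt1a1 at 1.29 and Cyp3a62 at 0.94. Xenobiotic genes were higher (0.00684, and 0.663 with an estimated correlation), with Gsta3 at 0.89 the 1 called over the list alone. Without control 1 the bile acid list had an adjusted p of 0.0685 and the xenobiotic list 0.109. Other markers moved with these lists: smooth muscle markers were higher by a median of 0.46 (camera adjusted p = 0.00684, and adjusted p = 0.663 with an estimated correlation), while B cell markers stood at 0.09 and were not called (0.264). Without control 2 the smooth muscle list turned down (0.851).

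NF-kB genes were lower in Peyer's patch (camera adjusted p = 2.09e-05, and 0.663 with an estimated correlation), with 0 of 21 called over all genes and 3 over the list alone. These were Socs3 at -1.33 ± 0.21, the interleukin gene Il1a at -1.86 ± 0.39 and the neutrophil chemoattractant gene Cxcl1 at -3.12 ± 0.68. The calls of the enterocyte, PPAR and NF-kB lists held without each library in turn. Defence genes were lower (0.00237, and 0.663 with an estimated correlation), with 4 of 18 over the list alone: Cxcl1, Tifa at -0.75, Duoxa2 at -1.21 and Nos2 at -1.67. That call was lost without control 3 (0.264) or antibiotics 1 (0.145). Th17 genes were lower (0.00243, and 0.663 with an estimated correlation), led by Il12b at -1.09 and Il21 at -1.59, with 0 of 14 called, and not without control 2 (0.139). T cell markers were lower (0.0121, and 0.663 with an estimated correlation), with 0 of 20 called and Icos at -0.57. They were not called without control 1, control 2 or antibiotics 2 (adjusted p up to 0.190).

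The remaining camera calls in Peyer's patch were of Paneth cell markers (up, adjusted p = 0.0121, Defa6 at 0.66), smooth muscle markers (up, Kcnmb1 at 0.72), immediate early and heat shock genes (down, 0.0185, Junb at -0.38), enteroendocrine cell markers (up, 0.0293, Nts at 0.94), goblet cell markers (up, 0.0293, Rep15 at 0.67), mitochondrially encoded genes (up, 0.0293, COX3 at 0.37), macrophage and dendritic cell markers (up, 0.0316, Csf1r at 0.31) and interferon-stimulated genes (down, 0.0373, Cxcl10 at -1.39). None had a member called over all genes. Over the list alone, 1 interferon gene was lower, Cxcl10, and 1 higher, Ifit1bl. With an estimated correlation the adjusted p was 0.663 for all of these but the mitochondrial list, at 0.689. All of them were lost without some library: without control 1 the Paneth (0.384), enteroendocrine (0.664), goblet (0.705), macrophage (0.169) and mitochondrial (0.248) lists were not called. Without antibiotics 2 the same lists (0.232, 0.281, 0.398, 0.0569 and 0.638), the smooth muscle list (0.129) and the interferon list (0.0853) were not called. Without control 2 the enteroendocrine (0.0609), macrophage (0.128), mitochondrial (0.305), immediate early (0.129) and interferon (0.228) lists were not called, and the smooth muscle list turned down (0.851). Without antibiotics 3 the enteroendocrine (0.0932), goblet (0.0581), macrophage (0.182) and immediate early (0.0598) lists were not called. Without antibiotics 1 the immediate early (0.251) and interferon (0.666) lists and without control 3 the interferon list (0.148) were not called. Quantile normalization ended the goblet (0.0679) and mitochondrial (0.127) calls, a block by replicate number ended the mitochondrial call (0.0566), and the B cell mean as a covariate ended the immediate early (0.125) and interferon (0.118) calls.

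Lists not called in Peyer's patch included B cell and germinal centre markers, plasma cell markers, cytotoxic lymphocyte markers, proliferation genes, stem cell markers, M cell markers, neutrophil and mast cell markers, neuron and glia markers, fibroblast and endothelial markers, and MHC class II, cholesterol and clock genes. Their camera adjusted p ran from 0.0685 to 0.852. Proliferation genes had a median of -0.04 (0.223), with Rrm2 at -0.28 ± 0.14. By camera that list was called lower in 3 of 11 other settings and leaned up in 1. The B cell list was called higher in 2 of 11 and leaned down in 3, and the M cell list was called higher in 2. The neuron, stem cell and cholesterol lists were called higher in 1 each. The chemokine gene Ccl19 of the fibroblastic and endothelial list stood at -0.63, Gzmb of the cytotoxic list, a name 2 genes share, at -1.10 and S100a9 of the neutrophil list at -1.85, none of them called. For MHC class II genes the median was 0.07 and the mean -0.07, and for germinal centre markers 0.06 and -0.0047, while camera leaned up for the first and down for the second.

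**Figure D4:**
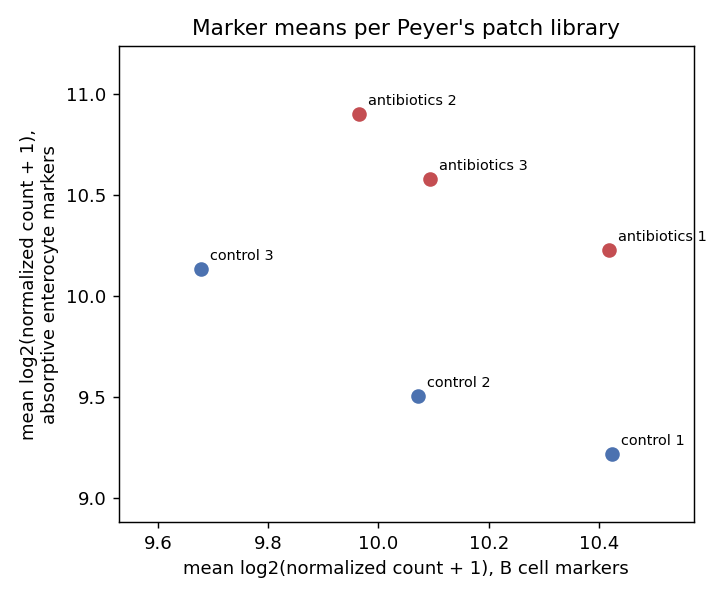
Mean log2(normalized count + 1) of the B cell markers (x axis) against that of the absorptive enterocyte markers (y axis) in the 6 Peyer's patch libraries, 1 point each. The enterocyte mean lies at 9.22 to 10.1 in controls and at 10.2 to 10.9 under antibiotics, while the B cell means of the groups overlap.

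The design also allows the 2 responses to be set against each other, gene by gene. None of 14944 genes passed the interaction test with limma: 0 were called, 1155 had an unadjusted p under 0.05, and voom called 0 with 1097. The largest evidence was for Nphs1, the kidney slit-diaphragm protein nephrin, whose response was lower in Peyer's patch by a log2 of -2.36 ± 0.33 (SE, limma adjusted p = 0.130). LOC103694585 came next at 1.92 (limma adjusted p = 0.285). Asns, the asparagine synthetase induced by amino acid shortage, came after it at 1.05 ± 0.19, with a change of -1.21 in ileum and -0.16 in Peyer's patch. Il18bp, a decoy receptor of interleukin 18, stood at 0.76 and the interferon-induced gene Ly6e at 0.64, both at an adjusted p of 0.416. Zfp653, Ndufa12, Fabp5, Pvt1 and Col9a3 completed the 10 smallest p-values at -1.56, 1.15, 0.68, -2.13 and -2.35. Without antibiotics 1 of Peyer's patch 1 gene was called. A gene called in ileum and not in Peyer's patch was thus not shown to respond differently in the 2 tissues.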

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

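The list tests of the difference between the tissues' responses were not part of the plan and were chosen after the data had been seen. They asked whether the response to antibiotics differed between Peyer's patch and ileum, as the interaction of limma's fit of all 12 libraries. By camera, 11 of 30 lists were called, all with a more positive log2 change in Peyer's patch than in ileum. That can be a smaller fall: proliferation genes had medians of -0.33 in ileum and -0.04 in Peyer's patch. Plasma cell markers (-0.25 and -0.04) also fell less there. Defence genes had medians of -0.63 over 16 members in ileum and -0.51 over 18 in Peyer's patch. With quantile normalization these were -0.48 and -0.49, so a smaller fall depends on the normalization. The differences given below are medians over members in the interaction fit, not differences between these medians. Over all genes, 0 members of the 11 lists were called. Adjusted over the list alone, 2 plasma cell and 1 enteroendocrine cell markers were called higher. With an estimated correlation none of the lists was called (adjusted p of at least 0.781), nor by fry (at least 0.631).

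The median response of absorptive enterocyte markers was higher in Peyer's patch than in ileum by a log2 of 0.51 (camera adjusted p = 0.000180), with Apoc3 at 0.93 ± 0.39 and Apoa1 at 0.73 ± 0.32. Proliferation genes fell less in Peyer's patch, a median difference of 0.30 (camera adjusted p = 0.000180), with Mcm5 at 0.54 ± 0.22. These 2 calls held without each of the 12 libraries in turn (adjusted p up to 0.0412 and 0.0328).

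The other 9 lists lost their call without at least 1 library. Bile acid handling genes differed by 0.47 (adjusted p = 0.0135, and up to 0.209 without a library), enteroendocrine cell markers by 0.42 (0.0242, up to 0.380), and fatty acid oxidation and PPAR target genes by 0.24 (0.0242, up to 0.129). Macrophage and dendritic cell markers differed by 0.29 (0.0135, up to 0.0529), plasma cell markers by 0.27 (0.0135, up to 0.0502) and Paneth cell markers by 0.60 (0.0135, up to 0.298). MHC class II presentation genes differed by 0.35 (0.0280, up to 0.392), microbe-responsive epithelial defence genes by 0.47 (0.0148, up to 0.203) and mitochondrially encoded genes by 0.37 (0.0148, up to 0.195). Of the 11 calls, 4 were kept without Peyer's patch antibiotics 3, 5 without Peyer's patch control 1, 6 without Peyer's patch antibiotics 2 and 7 without ileum antibiotics 1. Quantile normalization ended the calls of the MHC class II (0.0869), defence (0.257), mitochondrial (0.214) and Paneth (0.0535) lists. It also called the cholesterol synthesis list, with a more negative change in Peyer's patch (0.00575). A block by animal code called the circadian clock list in that direction (0.0295). Red blood cell genes, tested only here, were not called (0.810).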

How the results depend on the processing

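The covariates, voom, the pseudocount of 4 and the fit without jumping genes were chosen after the data had been seen. In ileum the 944 calls became 96 with a 2-fold minimum, 227 in 1 fit of both tissues, 284 with the smooth muscle mean as a covariate (262 of them shared) and 305 to 748 leaving out 1 library. The other settings run gave 798 to 1055. The 11 ileum lists became 0 with an estimated correlation and 6 to 12 leaving out 1 library. In Peyer's patch the 4 calls became 25 in 1 fit of both tissues (2 of them shared), 626 with the B cell mean as a covariate (539 higher, 87 lower), 0 with the smooth muscle mean, 0 with limma voom and 0 to 12 leaving out 1 library. At an unadjusted p under 0.05 limma had 890 genes, 806 with the smooth muscle mean, and voom 879. The 16 Peyer's patch lists became 0 with an estimated correlation and 10 to 17 leaving out 1 library. The interaction gave 0 genes with limma and 0 to 1 leaving out 1 library. Of the 63 called genes named in ileum, 17 were called under every setting run, and of the 4 in Peyer's patch 0 were. No named gene that was called reversed. Same-number correlations were -0.08 to 0.11 in ileum (1 of 3 numbers the best match), -0.24 to 0.32 in Peyer's patch (1 of 3) and -0.08 to 0.16 for a code across tissues (4 of 6), so pairing stays unsettled. Count-based size factors, a count-based Wald test and tests between tissues were not run.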

Other observations

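The 7 gene lists of this paragraph and the next were built after the calls had been seen. Neither their direction nor their p-values are therefore independent evidence, with either correlation. Among the lists so chosen, those for making and folding proteins were lower in treated ileum. Of 20 chaperones of the endoplasmic reticulum 16 were called lower, 18 adjusted over the list alone, among them Hyou1 at -0.87 ± 0.10 and the calcium-binding chaperone gene Calr at -0.73 ± 0.10 (SE of log2, n = 3). Of 20 cytosolic aminoacyl-tRNA synthetases, which charge transfer RNAs, 16 were called lower, 18 adjusted over the list alone, with Yars1 at -0.80 ± 0.09 and Gars at -0.57 ± 0.07. Of 18 genes of the amino acid response factor Atf4 and of serine synthesis 8 were lower; adjusted over the list alone 11 were lower and 1 higher, Trib3 at 0.47, with Asns at -1.21 ± 0.12 and Mthfd2 at -0.90 ± 0.12. Of 12 immunoproteasome and peptide loading genes 6 were lower, 9 adjusted over the list alone, with Tap1 at -0.78 ± 0.08. The camera adjusted p of these lists were 2.77e-17, 2.80e-16, 2.00e-07 and 1.38e-09, and the adjusted p = 0.0735, 0.0320, 0.0735 and 0.0618 with an estimated correlation.

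Glycolysis genes were lower in treated ileum, 7 lower and 1 higher of 21 called, with 8 lower and 1 higher adjusted over the list alone. The kinase genes Hk2 and Pfkfb3 stood at -1.08 ± 0.13 and -1.43 ± 0.13 (camera adjusted p = 9.45e-05; adjusted p = 0.145 with an estimated correlation). Sestrin, autophagy and FOXO target genes were higher, 10 of 17 called; adjusted over the list alone 11 were higher and 1 lower, Foxo3 at -0.21, with the autophagy kinase gene Ulk1 at 0.75 ± 0.09 and Bnip3 at 1.05 ± 0.15 (1.36e-09; 0.0320 with an estimated correlation). Gluconeogenesis genes were not called as a list in ileum (0.0890; 0.367 with an estimated correlation), with 2 higher and 1 lower of 11. In Peyer's patch limma called 1 member of these lists, Pck1. By camera the sestrin list was higher there (3.76e-05; 0.0562 with an estimated correlation), as was gluconeogenesis (0.00101; 0.235), and the chaperone list (0.0244; 0.626) and the Atf4 list (0.0418; 0.235) were lower. The glycolysis, synthetase and immunoproteasome lists were not called there (adjusted p of at least 0.0824).

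The tests of the enterocyte and proliferation patterns, the bound on animals of an outbred stock, the search for partners that jump themselves both covariates and the look at smooth muscle means across splits were chosen after the result was seen; the splits were planned. With 3 libraries against 3 there are 10 splits, which cannot give a share under 0.05. In ileum 1 of 10 splits, the real one, gave as many as 944 calls, and the highest other gave 3. In Peyer's patch 2 of 10 gave at least the real 4, and in the interaction 10 of 10 gave at least the real 0, with a highest other of 1.

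Few genes were called in Peyer's patch, where the highest other split called 1230 genes, which points to a structure of the samples: it sets controls 1 and 2 with antibiotics 1 against the rest. A lymphoid share that varies within groups is consistent with the 626 calls under the B cell covariate, beside 4 at most in any other split, though the B cell means overlap across the split of 1230. A muscle wall share that varies within groups stays open. Its covariate left 0 calls, which met the bound first written against it, but the smooth muscle means, at 8.69 to 9.90 against 10.1 to 10.8, part that same split, so the covariate cannot be set apart from it. Both remain hypotheses, with 3 libraries a group and 1 more term in the fit.

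Enterocyte markers were higher in Peyer's patch under antibiotics. A larger share of epithelium as the whole cause is argued against. The enterocyte mean moved by 0.95 and the mean of goblet, stem and enteroendocrine markers by 0.26. That was a gap of 7.93 pooled SDs, from 3 libraries a group, between groups that did not overlap. Paneth cell markers, added to the test later, moved by 0.35, and the gap was 4.48 pooled SDs against them alone and 11.1 with all 4 lists. More epithelium as a part of the cause stays open, since these other epithelial lists moved up too. A lower share of B cells is argued against. The B cell marker mean itself was not lower, at 10.06 ± 0.37 in controls and 10.16 ± 0.23 under antibiotics (SD, n = 3), with overlapping groups. The test through other cell types argued against it by a close margin. The highest median of 5 of them, smooth muscle at 0.46, lay below the lower quartile of the enterocyte list at 0.52. T cell and fibroblast markers stood at -0.18 and -0.01. More mature villus tissue in the treated pieces, or a response to antibiotics, stays open.

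Proliferation genes were lower in treated ileum, their mean by -0.31. Fewer crypts as the whole cause are argued against: stem cell markers, median 0.11, moved apart from them by 4.75 pooled SDs with no overlap of the groups, and Paneth cell markers by 2.80. A part of it stays open, since the Paneth mean moved by -0.14 and the stem cell list's called gene, Cdca7, by -0.35. Fewer lymphoid cells stay open, because B cell markers, tested first and low in ileum, had a median of 0.13, germinal centre B cell markers -0.09 and T cell markers -0.22, all above the upper quartile of the proliferation genes at -0.23, while cytotoxic lymphocyte markers at -0.34 and plasma cell markers at -0.25 lay within their quartiles. A response of dividing cells to antibiotics may also remain, untested, as a hypothesis.

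Genes such as Capns1, Ncbp2, LOC100912481 and, in ileum, Aldh18a1 jumped 8-fold or more between libraries of 1 group. Their median correlation between tissues across animal codes was 0.0983 over 118 genes, beside 0.110 for all genes. In the first partner search 101 of 140 had an opposite partner and so did a median of 101 shuffled ones, which decides nothing; in the second, 4 had a partner that itself jumps, beside a shuffled median of 6.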
